A study of Homo sapiens with 16 samples.

How the data were processed

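The series was read from 1 table of 49731 rows and 16 columns, 1 column per library, every column used. Per the labels the libraries are ribosomal-RNA-depleted, paired-end with reads of 50 bases, and aligned to GRCh38. The deposited values are RPKM as computed by the authors; the submitters' notes name HISAT2, StringTie and limma without versions and without saying which step each performed. Of the rows, 46603 have an identifier and version in GENCODE 29, 2777 were named through another version of the same identifier, 40 through a gene name table and 311 had no name. The 40 pseudoautosomal rows of the Y chromosome, all at 0, were left out. Sex-linked genes are not reported here.

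Values were checked before use. Multiplied by the exon length in the basic GENCODE 29 annotation, 99.82 to 99.87% of values fall on whole multiples of 1 step per library, within 0.05, which gives 42.6 M to 74.0 M reads per library and recovered read counts for 12929 tested genes (94.4%). The 2 libraries of each group were compared for duplicates and none were found. Genes with at least 1 RPKM in at least 2 libraries were kept, 13697 in number, 11414 of them protein-coding. The median standard error is 0.0665 log2 units for a comparison of 2 groups and 0.0941 for a difference of responses.

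Libraries were grouped by the labels into 8 groups of 2. Each gene was fitted on log2(RPKM + 1) with 8 group means in limma (lmFit, contrasts.fit, and eBayes with a trend), all libraries in 1 fit, and p-values were adjusted by Benjamini and Hochberg within each comparison. A gene changed if its adjusted p was below 0.05. Because 1 is added, the fold change on this log2(value + 1) scale understates that of genes near or below 1 RPKM, such as the chemokines. The 10 comparisons, the filter, the scale, the tests and their alternatives, and 24 gene lists were fixed before the data were examined. The comparisons of DMSO with PBS cells, the difference of the 2 interferon responses of parental cells, the voom alternative and the fit without the GSK126 group were chosen after seeing the data.

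Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison; the alternatives were an estimated correlation and fry. Counts of genes adjusted over the list alone are given beside the counts over all genes. Interferon-induced sets were chosen on libraries of the other experiment (adjusted p below 0.05 and at least 2-fold higher), so choice and test share no library. The responses of the experiments differ, so a set can still favour one side. CXCL9, CXCL10 and CXCL11, weak in DMSO cells, are only in the set chosen in wild-type PBS cells. Overlaps were tested with Fisher's exact test. Voom was run on the recovered reads with median-of-ratios scaling. Other alternatives were a pseudocount of 0.1, no filter or 5 RPKM, 3 other scalings, a replicate block, no trend, a robust fit, each experiment fitted alone and single libraries left out.

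Genes are named by rule: a fixed set in any comparison (among them ARID1A, EZH2, IRF1, CIITA, CD274, CXCL9, CXCL10 and CXCL11), the 8 largest rises and falls of each, and the 4 genes of each list with the smallest p-values; a gene named so in one comparison may be given in another. MT-ND6 is named outside this rule, as it moved against its list. Not analysed here are isoforms, intronic reads, the reads themselves and any protein. In a simulation on 12536 genes, all libraries were drawn from the wild-type PBS means with the same spread for every gene. In the libraries standing for wild-type interferon, 200 genes picked at random were changed. Of these changes 98% at 2-fold and 73% at 1.5-fold were recovered, and 14 of 185 calls were false (7.57%). The real comparisons hold far more calls and groups of unequal spread, so these rates need not apply to them. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.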

Results

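The series holds 16 RNA libraries of OVCA429, an ovarian carcinoma cell line, in 8 groups of 2. One experiment crosses ARID1A genotype (wild type or labelled knockout) with interferon gamma for 8 h against PBS. The other keeps wild-type cells and crosses 48 h of GSK126, an inhibitor of the histone methyltransferase EZH2, against DMSO, with or without 8 h of interferon gamma. ARID1A is a subunit of the SWI/SNF chromatin remodeller and EZH2 is the catalytic subunit of PRC2, which marks silent genes. Of the rows in the deposited table, 13697 genes passed the filter and were tested. Levels are means ± SD in RPKM (n = 2) and changes are log2 values ± standard error. Each gene list is given with the genes called higher and lower, the same counts adjusted over the list alone, and the median change. P-values measure only the spread between these libraries. The labels do not say whether the 2 libraries of a group are separate cultures, so that spread may be technical.

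ARID1A transcript was not lower in the cells labelled knockout. ARID1A (ENSG00000117713.18, chromosome 1, 26693236 to 26782110) stood at 9.69 ± 0.71 RPKM there and at 8.36 ± 0.09 in wild-type cells on PBS, a change of 0.19 ± 0.062 (adjusted p = 0.0243). The knockout libraries held 9.19 and 10.2 RPKM against 8.43 and 8.3, and the call was lost with all libraries scaled to one sum (0.18, adjusted p = 0.0575). With interferon the levels were 4.0 ± 0.31 and 3.63 ± 0.13 RPKM (adjusted p = 0.17 for the difference, 0.0414 under quantile normalization). ARID1A was lower with interferon in wild type (-1.02) and in the knockout (-1.10). It belongs to a set of genes, described below, for which a batch of the untreated libraries cannot be told from an effect of treatment. A short insertion or deletion can leave a transcript in place, so the table neither shows nor excludes loss of the protein, and each direction given here for the knockout rests on its label. The titles name all knockout libraries as one line, AC17, and the others as OVCA429, so a difference between clones cannot be told from an effect of genotype. SWI/SNF subunits as a list did not pass between the lines (10 higher and 4 lower of 23, list alone 10 and 4, median 0.067, adjusted p = 0.221). EZH2 (ENSG00000106462.10, chromosome 7, 148807383 to 148884321), the target of GSK126, fell by 0.43 ± 0.042 in the knockout (adjusted p = 2.63e-06) and changed by 0.15 ± 0.042 with GSK126 (adjusted p = 0.0171). That call was lost with the experiment fitted alone (adjusted p = 0.0653) and without the first DMSO (adjusted p = 0.107) or second GSK126 library (adjusted p = 0.0745), at values of 0.12 to 0.15.

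Interferon gamma switched on antigen presentation, chemokines, guanylate-binding proteins and antiviral genes in wild-type cells. Both arms of antigen presentation rose, HLA-DRA and CIITA from close to 0. POLR2A, the largest RNA polymerase II subunit, had the largest fall. In all, 2471 genes rose and 2187 fell, 174 and 56 of them by at least 2-fold. The largest rises were GBP1 (4.80), GBP4 (4.74), GBP5 (4.38) and GBP2 (3.60), GTPases that attack pathogen membranes, the tryptophan-degrading enzyme IDO1 (4.46), the transcription factors IRF1 (4.01) and BATF2 (3.63) and the tRNA synthetase WARS (3.53). GBP1 (ENSG00000117228.9, chromosome 1, 89052319 to 89065360) went from 9.04 ± 0.16 to 280 ± 12 RPKM, and IRF1 (ENSG00000125347.13, chromosome 5, 132481609 to 132490798) from 12.6 ± 0.014 to 218 ± 2 RPKM (4.01 ± 0.049, adjusted p = 5.56e-15). Among JAK-STAT and IRF regulators (12 higher and 0 lower of 16, list alone 12 and 1, median 1.47, adjusted p = 2.71e-13), IRF9 (2.49) and IRF8 (2.13) also rose. MHC class I genes rose throughout (18 higher and 0 lower of 18, list alone 18 and 0, median 1.0, adjusted p = 7.04e-22), with the peptide transporter TAP1 (3.03), the class I transactivator NLRC5 (2.34) and HLA-E (2.02). MHC class II genes did the same (13 higher and 0 lower of 13, list alone 13 and 0, median 2.05, adjusted p = 6.51e-17), with the class II transactivator CIITA (2.21), HLA-DRA (3.46), HLA-DRB1 (3.03) and the invariant chain CD74 (2.05). HLA-DRA (ENSG00000204287.13, chromosome 6, 32439842 to 32445046) reached 11.5 ± 0.024 RPKM from 0.144 ± 0.07.

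CXCL9, CXCL10 and CXCL11, which draw T cells through the receptor CXCR3, appeared at low levels in wild-type cells. CXCL10 (ENSG00000169245.5, chromosome 4, 76021117 to 76023497) reached 3.60 ± 0.36 RPKM (2.18 ± 0.10, adjusted p = 2.41e-09), CXCL11 (ENSG00000169248.12, chromosome 4, 76033682 to 76041415) 1.80 ± 0.052 (1.48, adjusted p = 5.12e-08) and CXCL9 (ENSG00000138755.5, chromosome 4, 76001275 to 76007488) 1.20 ± 0.15 (1.13, adjusted p = 8.96e-07). CXCL9 was listed at 0 in both wild-type libraries on PBS. With the smaller rise of CXCL16 (0.39) the chemokine list moved as a whole (5 higher and 0 lower of 5, list alone 5 and 0, median 1.13, adjusted p = 2.86e-05). Guanylate-binding proteins (6 higher and 0 lower of 6, list alone 6 and 0, median 3.99, adjusted p = 1.64e-13) and antiviral genes (38 higher and 0 lower of 39, list alone 38 and 0, median 1.13, adjusted p = 1.93e-34) rose too, the latter with PARP14 (2.90), PARP9 (2.23), XAF1 (2.82) and IFIT3 (2.47). Checkpoint ligands and immune effectors (19 higher and 0 lower of 19, list alone 19 and 0, median 1.60, adjusted p = 2.99e-25) included the adhesion molecule ICAM1 (2.82), the apolipoprotein APOL6 (2.84) and the PD-1 ligand CD274 (0.79). NF-kB cytokines rose less (3 higher and 0 lower of 5, list alone 4 and 0, median 0.49, adjusted p = 0.00632), led by the feedback inhibitors TNFAIP3 (0.62) and NFKBIA (0.54).

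Among the falls, POLR2A (ENSG00000181222.15, chromosome 17, 7484366 to 7514616) went from 19.8 ± 0.3 to 3.87 ± 0.32 RPKM (-2.10 ± 0.07, adjusted p = 5.63e-11). Other falls were the matricellular protein CTGF (-1.73), the actin regulator RAPH1 (-1.53) and the histone methyltransferase KMT2D (-1.38). Mitochondrial messages fell at the NADH dehydrogenase genes MT-ND4L (-1.46), MT-ND4 (-1.41) and MT-ND5 (-1.14) (2 higher and 7 lower of 13, list alone 2 and 7, median -0.79, adjusted p = 0.00023, adjusted p = 0.236 with an estimated correlation). Another NADH dehydrogenase gene, MT-ND6, rose instead (1.08), and it is among the 174 genes raised at least 2-fold. The proliferation marker MKI67 (-1.16) fell, from 72.0 ± 0.27 to 31.8 ± 2.9 RPKM. All genes named in this paragraph as falling belong to a set of 341, described below, for which a batch of the untreated libraries stays open. Scaling every library to one sum left 4932 calls but put only 25.9% of them above 0 against 53% with the deposited values, so the balance of small rises and falls depends on the scale. Without the second PBS library 3053 genes were called.

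Cells labelled knockout differed from wild type on PBS in many genes, lineage and baseline immune genes among them. They carried a retinaldehyde dehydrogenase that wild-type cells hardly express and held far less of an S100 protein and of cyclin D2. Of 6206 changed genes 2898 were higher and 3308 lower, 119 and 256 by at least 2-fold. Untreated DMSO cells of the parental line differed from parental PBS cells in 5884 genes, 26 higher and 132 lower by at least 2-fold. Many calls can thus arise without a change of genotype. ALDH1A1 (ENSG00000165092.12, chromosome 9, 72900662 to 73080442) stood at 33.8 ± 1 RPKM against 0.113 ± 0.029 (4.97 ± 0.066, adjusted p = 1.88e-14). Other rises were the thyroid hormone deiodinase DIO2 (4.28), calretinin (3.59 for CALB2), connexin 40 (3.58 for GJA5), the squamous envelope protein IVL (2.81) and the pregnancy-specific glycoproteins PSG5 (2.68) and PSG1 (2.65). S100A14 (ENSG00000189334.8, chromosome 1, 153614255 to 153616986), a calcium-binding protein, was at 1.97 ± 0.018 against 31.9 ± 0.87 RPKM (-3.47 ± 0.084, adjusted p = 6.66e-12), and the adhesion molecule NRCAM (-2.79), cyclin D2 (-2.57 for CCND2) and the Wnt kinase TNIK (-2.52) also fell.

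MHC class I genes and guanylate-binding proteins were lower before any interferon was given, though as lists only with the preset correlation (adjusted p = 0.22 and 0.23 with an estimated one). Antiviral genes went both ways (13 higher and 13 lower of 39, list alone 13 and 16, median -0.093, adjusted p = 0.542). MHC class I genes fell (1 higher and 16 lower of 18, list alone 1 and 16, median -0.58, adjusted p = 3.77e-08, adjusted p = 0.22 with an estimated correlation), with HLA-F (-1.63), NLRC5 (-1.25) and HLA-B (-1.14). HLA-B stood at 168 ± 2.1 RPKM against 370 ± 11. HLA-B and MHC class I as a list were also lower in parental DMSO cells than in parental PBS cells, as given below. A lower class I baseline is thus not particular to the knockout label. Guanylate-binding proteins fell too (0 higher and 6 lower of 6, list alone 0 and 6, median -0.95, adjusted p = 5.66e-05, adjusted p = 0.23 with an estimated correlation), with GBP2 (-1.67), GBP6 (-1.44) and GBP1 (-1.01), as did checkpoint and effector genes (2 higher and 13 lower of 19, list alone 2 and 13, median -0.34, adjusted p = 0.00144, adjusted p = 0.263 with an estimated correlation), with APOL6 (-1.22), ICAM1 (-1.11) and CASP1 (-0.80). The PD-1 ligand CD274 (ENSG00000120217.13, chromosome 9, 5450503 to 5470566) went the other way, 17.7 ± 1.2 against 12.4 ± 0.15 RPKM (0.48 ± 0.058, adjusted p = 1.71e-05), and IRF1 fell by 0.59. MHC class II genes were mixed (2 higher and 4 lower of 13, list alone 2 and 4, median -0.039, adjusted p = 0.534), with CTSS (-1.46) and HLA-DMA (1.05) moving apart.

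Lineage genes differed between the lines. Parental DMSO cells, described below, also held less mesenchymal message than parental PBS cells, so a lower level of that list is not particular to the knockout label. Mesenchymal genes fell (2 higher and 7 lower of 11, list alone 2 and 7, median -0.43, adjusted p = 0.0417, adjusted p = 0.243 with an estimated correlation), with vimentin at 22.6 ± 2.4 against 76.6 ± 1.7 RPKM (-1.72 for VIM) and fibronectin lower (-0.88 for FN1). Epithelial genes were split (4 higher and 7 lower of 15, list alone 4 and 7, median -0.078, adjusted p = 0.513): E-cadherin fell (-1.09 for CDH1) and the keratins KRT18 (0.67) and KRT8 (0.59) rose. Of the ovarian line markers (1 higher and 4 lower of 6, list alone 1 and 4, median -0.54, adjusted p = 0.0417, adjusted p = 0.23 with an estimated correlation), WFDC2 (-2.21), MUC16 (-1.22) and MECOM (-0.69) fell and the lineage factor PAX8 (0.67) rose. p53 targets rose (8 higher and 3 lower of 16, list alone 8 and 3, median 0.22, adjusted p = 0.0232, adjusted p = 0.23 with an estimated correlation), with BAX (0.69), TP53I3 (0.67) and FDXR (0.69), and so did proliferation genes (13 higher and 3 lower of 26, list alone 13 and 4, median 0.10, adjusted p = 0.0417, adjusted p = 0.552 with an estimated correlation), with CDC20 (0.55) and CCNE1 (0.54). Ribosomal protein genes leaned up (9 higher and 1 lower of 24, list alone 9 and 1, median 0.092, adjusted p = 0.021, adjusted p = 0.688 with an estimated correlation), with RPL18 (0.60). Under quantile normalization the calls for ribosomal protein, proliferation and ovarian line genes were lost (medians 0.017, 0.074 and -0.43, adjusted p = 0.593, 0.25 and 0.0623). PRC2 subunits (3 higher and 3 lower of 12, list alone 3 and 3, median -0.062, adjusted p = 0.896) held opposed changes in JARID2 (0.81) and EZH2 (-0.43), and Polycomb-type developmental genes did not pass (10 higher and 2 lower of 26, list alone 10 and 3, median 0.038, adjusted p = 0.221) although SOX9 (0.58) rose. Only 26 of the 52 listed developmental genes passed the filter. Of the marker lists for other cell types only CSF1R among 12 leukocyte genes, 3 of 10 fibroblast genes (FAP, LUM and COL1A1) and 2 of 8 endothelial genes (ESAM and EGFL7) were expressed enough to test, with CSF1R lower (-1.90) and LUM (1.24) and FAP (0.78) higher in the knockout.

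Interferon gamma also acted on the cells labelled knockout, through the same families. Guanylate-binding proteins and MHC class I genes climbed, GBP1 to 352 ± 27 RPKM against 280 ± 12 in wild type. MHC class II genes and the CXCR3 chemokines rose but stayed below wild type. In the knockout 2946 genes rose and 2373 fell with interferon, 200 and 73 by at least 2-fold, with GBP1 (6.15), GBP4 (5.34), IDO1 (4.75), IRF1 (4.58), BATF2 (4.19) and ICAM1 (4.08) on top. MHC class I (18 higher and 0 lower of 18, list alone 18 and 0, median 1.25, adjusted p = 1.22e-23) included TAP1 (3.76) and NLRC5 (3.32), and MHC class II (12 higher and 0 lower of 13, list alone 13 and 0, median 1.27, adjusted p = 3.85e-11) HLA-DRA (2.32) and CTSS (2.10). Chemokines (5 higher and 0 lower of 5, list alone 5 and 0, median 0.50, adjusted p = 0.00265) rose with CXCL10 (1.38) and CXCL11 (0.77), and CXCL9 by 0.33 (adjusted p = 0.0153). CIITA (ENSG00000179583.18, chromosome 16, 10866222 to 10943021) reached 2.01 ± 0.0017 RPKM against 3.79 ± 0.094 in wild type. POLR2A fell here as well (-2.10 ± 0.07, adjusted p = 4.53e-11), with RIPOR1 (-1.61), SRRM2 (-1.56) and MT-ND4 (-1.48). Of the calls, 55.4% were rises with the deposited values and 23.1% of 5620 with every library scaled to one sum; without the first interferon library of the knockout 3529 genes were called.

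With interferon in both genotypes, the knockout held less MHC class II and chemokine message and more PD-1 ligand. These lists pass only with the preset correlation (adjusted p = 0.127 and 0.127 with an estimated one). Here 3211 genes were higher and 3366 lower, 110 and 255 by at least 2-fold, led by ALDH1A1 (5.27) and, downward, S100A14 (-3.70) and the TNF receptor adaptor TRAF1 (-3.22). MHC class II genes were lower (0 higher and 11 lower of 13, list alone 0 and 11, median -0.68, adjusted p = 2.88e-05, adjusted p = 0.127 with an estimated correlation): HLA-DRA stood at 3.99 ± 0.24 against 11.5 ± 0.024 RPKM (-1.33 ± 0.059, adjusted p = 1.55e-09), with cathepsin S (-0.94 for CTSS), CD74 (-0.86), HLA-DPA1 (-0.87) and CIITA (-0.67). All chemokines tested were lower (0 higher and 5 lower of 5, list alone 0 and 5, median -0.78, adjusted p = 0.00586, adjusted p = 0.127 with an estimated correlation): CXCL10 1.60 ± 0.27 against 3.60 ± 0.36 RPKM (adjusted p = 2.3e-05), CXCL9 0.278 ± 0.06 against 1.20 ± 0.15 (adjusted p = 1.82e-05), CXCL11 0.816 ± 0.083 against 1.80 ± 0.052 (adjusted p = 0.000116), and CCL5 (-1.0). Antiviral genes leaned up (20 higher and 5 lower of 39, list alone 21 and 5, median 0.16, adjusted p = 0.00754, adjusted p = 0.609 with an estimated correlation), with RSAD2 (0.96), IFIT3 (0.61) and OAS3 (0.51). MHC class I did not pass (4 higher and 8 lower of 18, list alone 4 and 8, median -0.082, adjusted p = 0.181; 0.0484 under quantile normalization), with HLA-F (-1.40) lower and HLA-E (0.63) higher. CD274 reached 36.4 ± 2.5 against 22.2 ± 0.48 RPKM (0.69 ± 0.058, adjusted p = 5.56e-07), and IRF1 showed no detected difference (-0.018 ± 0.049, adjusted p = 0.795). Parental DMSO cells with interferon, from the other experiment, held less chemokine than the knockout. Their libraries had 0.271 and 0.311 RPKM of CXCL10, 0.0608 and 0.0778 of CXCL9, and 0.151 and 0.0878 of CXCL11. For these genes parental cultures differed by more than the genotypes. HLA-DRA (8.73 and 8.51) and CIITA (4.07 and 4.04) were above the knockout there.

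The size of the interferon response itself differed between the genotypes, and not in one direction. MHC class I as a list rose by more in the knockout, and so did GBP1 and ICAM1 from a lower start. MHC class II as a list and CXCL9, CXCL10 and CXCL11 rose by less on the log2(RPKM + 1) scale. In parental cells MHC class I also rose by more on DMSO than on PBS, and the same chemokines by less, as given below. Neither of these differences is thus particular to the genotype label. MHC class II as a list did not pass in that comparison of parental cells. The test of the difference called 129 genes, 74 with a positive difference (knockout minus wild type) and 55 with a negative one. At the top were GBP1 (1.35 ± 0.11, adjusted p = 2.08e-05), ICAM1 (1.26), APOL6 (1.15), the transcription factor ETV7 (1.13), NLRC5 (0.98) and the immunoproteasome subunit PSMB9 (0.95). Among the most negative were FRMD3 (-1.67), HLA-DRA (-1.14 ± 0.084, adjusted p = 1.08e-05), HLA-DMA (-1.02), TRAF1 (-0.99) and CSF1 (-0.89). TRAF1 and CSF1 lost their calls with a pseudocount of 0.1 (-0.29, adjusted p = 0.679, and -0.081, adjusted p = 0.928) and changed sign with voom. MHC class I passed as a list (10 higher and 0 lower of 18, list alone 15 and 0, median 0.43, adjusted p = 3.2e-26), and so did MHC class II in the other direction (1 higher and 7 lower of 13, list alone 1 and 10, median -0.64, adjusted p = 1.1e-15), with CIITA at -0.63 ± 0.092 (adjusted p = 0.00401). CIITA and HLA-DRA start at or near 0, so the scale matters. With a pseudocount of 0.1 both lost their calls, CIITA at -0.54 (adjusted p = 0.479) and HLA-DRA at -0.25 (adjusted p = 0.731), while the list held (adjusted p = 3.22e-06). With voom on recovered reads, chosen after the data were seen, the class II list was lost (median -0.27, adjusted p = 0.192) and HLA-DRA turned to 2.56 (adjusted p = 0.138). The chemokines (0 higher and 3 lower of 5, list alone 0 and 3, median -0.71, adjusted p = 2.6e-05) included CXCL9 (-0.81 ± 0.14, adjusted p = 0.00987), CXCL10 (-0.81 ± 0.15, adjusted p = 0.0185) and CXCL11 (-0.71 ± 0.13, adjusted p = 0.0228). With a pseudocount of 0.1 their calls were lost at values no smaller: -1.99 for CXCL9 (adjusted p = 0.258), -0.95 for CXCL10 (adjusted p = 0.47) and -1.71 for CXCL11 (adjusted p = 0.235). With voom CXCL9 was at -4.35 (adjusted p = 0.0589) and CXCL10 at -0.44 (adjusted p = 0.92). The list held on both scales (adjusted p = 0.00902 and 0.0132). Guanylate-binding proteins (3 higher and 1 lower of 6, list alone 4 and 2, median 0.54, adjusted p = 0.000764, adjusted p = 0.248 with an estimated correlation) and antiviral genes (8 higher and 0 lower of 39, list alone 18 and 0, median 0.18, adjusted p = 4.46e-12, adjusted p = 0.102 with an estimated correlation) leaned up. CD274 (0.21 ± 0.082, adjusted p = 0.341) had no detected difference in response. The 202 genes raised at least 2-fold in the DMSO libraries, which share no library with the test between genotypes, had a median of 0.18 (quartiles -0.13 and 0.40, p = 3.35e-09, p = 0.023 with an estimated correlation), 41 called higher and 16 lower. Quantile normalization gave a median of 0.105. Sets chosen anew with a pseudocount of 0.1 (289 genes) and voom (283 genes) had 48 and 54 called higher, 6 and 8 lower. The 41 fell to 21 without the second wild-type PBS library, 24 and 23 without the wild-type interferon libraries in turn and 23 without the first knockout interferon library. The same genes stood slightly lower in the knockout once interferon was present (median -0.11, p = 0.0042, p = 0.212 with an estimated correlation). The 129 became 76 without the first wild-type PBS library and 63 without the second, 61 and 70 without the wild-type interferon libraries in turn, 79 without the second knockout PBS library and 73 without the first knockout interferon library.

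**Figure D1:**
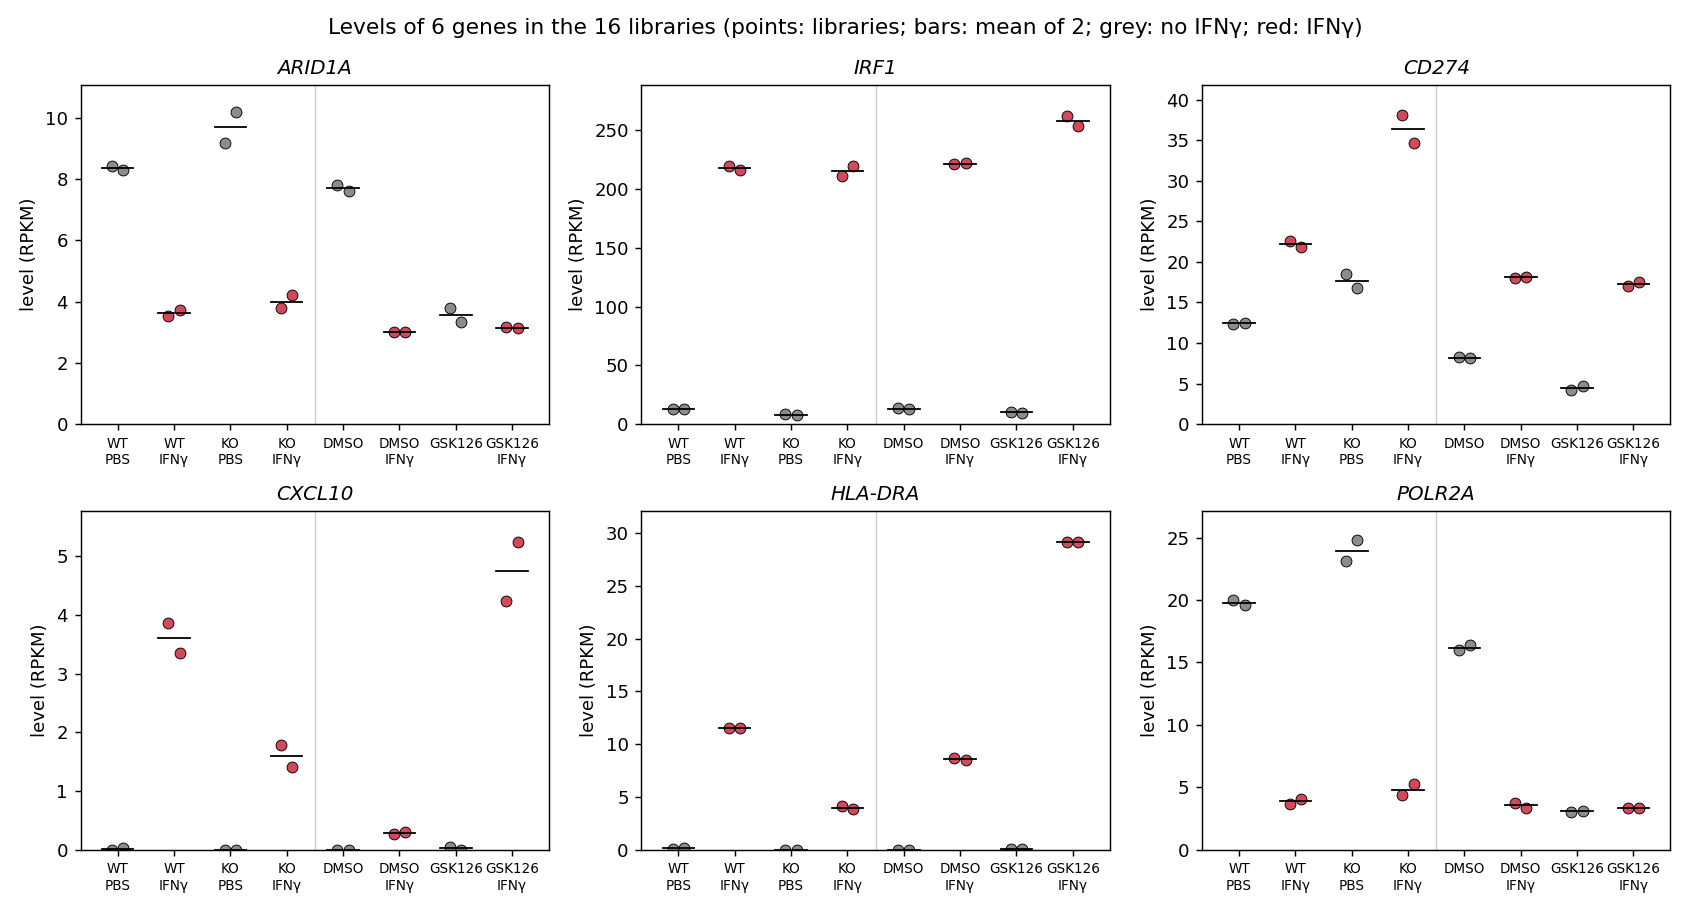
Levels in RPKM (vertical axes, linear, from 0) of 6 genes across the 8 groups (horizontal axes); points are single libraries, bars the mean of 2, red with interferon gamma and grey without. CXCL10 means with interferon are 3.60 (wild type), 1.60 (knockout), 0.290 (DMSO) and 4.74 RPKM (GSK126), and POLR2A is at 3.08 RPKM with GSK126 alone against 16.2 with DMSO.

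With GSK126 alone cholesterol, stress-response and histone genes were higher and POLR2A, MKI67 and SOX9 lower. CXCL9, CXCL10, CXCL11 and CIITA showed no detected change (adjusted p = 0.985, 0.833, 0.973 and 0.734). POLR2A and MKI67 belong to a set, described below, for which a batch of the untreated libraries cannot be told from an effect of treatment. As lists the rises pass only with the preset correlation (adjusted p = 0.254, 0.254 and 0.254 with an estimated one). Most changes were small. Falls led the list, with POLR2A at the top as after interferon. Of 4172 changed genes 1689 rose and 2483 fell, but only 8 and 49 by at least 2-fold. Among the rises were the metallothionein MT1F (1.16), the chemokine scavenger ACKR3 (1.15), the differentiation inhibitor ID2 (1.12), the glutathione-degrading enzyme CHAC1 (1.10) and the lysosomal glycoprotein GPNMB (1.03). Cholesterol genes rose (16 higher and 0 lower of 20, list alone 18 and 0, median 0.32, adjusted p = 4.14e-10, adjusted p = 0.254 with an estimated correlation), with INSIG1 (0.71), MVD (0.59), FDPS (0.49) and DHCR7 (0.41). Stress-response genes rose (11 higher and 0 lower of 17, list alone 12 and 1, median 0.36, adjusted p = 1.21e-05, adjusted p = 0.254 with an estimated correlation): the transcription factor DDIT3 went from 6.41 ± 0.32 to 13.3 ± 1.8 RPKM (0.95 ± 0.096, adjusted p = 1.17e-05), with HERPUD1 (0.55) and ATF3 (0.54). Histone genes rose (11 higher and 0 lower of 11, list alone 11 and 0, median 0.39, adjusted p = 4.14e-10, adjusted p = 0.254 with an estimated correlation), with HIST1H4H (0.54) and HIST1H1C (0.48). Antiviral genes leaned up (15 higher and 3 lower of 39, list alone 18 and 3, median 0.12, adjusted p = 0.000392, adjusted p = 0.541 with an estimated correlation), with CMPK2 (0.60), RSAD2 (0.51) and MX2 (0.47).

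POLR2A fell from 16.2 ± 0.31 to 3.08 ± 0.062 RPKM with GSK126 (-2.08 ± 0.07, adjusted p = 1.66e-09), and QSER1 (-1.59), ZFHX4 (-1.42), KMT2D (-1.41), USP14 (-1.39) and ARID1A itself (-0.94) fell with it. MKI67 dropped from 72.9 ± 1.8 to 25.5 ± 0.8 RPKM (-1.48), with the mitotic kinases PLK1 (-0.93) and AURKA (-0.62). Cyclin E2 rose (0.87 for CCNE2). Proliferation genes as a list did not pass (10 higher and 13 lower of 26, list alone 11 and 14, median -0.16, adjusted p = 0.377). Polycomb-type developmental genes, the class that PRC2 silences, did not pass (3 higher and 6 lower of 26, list alone 3 and 6, median -0.0049, adjusted p = 0.765), and SOX9 (-1.04) and GATA3 (-0.81) fell. Only 26 of the 52 listed genes passed the filter of at least 1 RPKM in at least 2 libraries. The list therefore cannot show weak release of silent genes. PRC2 subunits were not moved as a list either (1 higher and 5 lower of 12, list alone 1 and 5, median -0.10, adjusted p = 0.316), with SUZ12 (-0.42) lower. The PD-1 ligands CD274 (-0.75) and PDCD1LG2 (-0.89) fell, CD274 from 8.21 ± 0.14 to 4.49 ± 0.36 RPKM. Many of the falls are shared with interferon: of 341 genes lowered by interferon in both genotypes, chosen on libraries apart from these, 286 were lower and 4 higher with GSK126 alone (median -0.59). The first and second GSK126 libraries differ more than those of any other group (chi-square 15.9 per degree of freedom against 2.64 for wild type on PBS). Median-of-ratios scaling put 50.6% of the calls above 0 against 40.5%.

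Interferon gamma in the DMSO cells raised guanylate-binding proteins, IRF1 and both MHC classes, as in PBS cells, with some lists differing in size. CXCL10 rose by little on the log2(RPKM + 1) scale. MHC class I rose by more than in PBS cells, by a test of the difference added after the data were seen (4 higher and 0 lower of 18, list alone 16 and 0, median 0.24, adjusted p = 1.89e-15). In that test, with 143 genes called, antiviral genes (7 higher and 0 lower of 39, list alone 15 and 2, median 0.08, adjusted p = 8.62e-06, adjusted p = 0.353 with an estimated correlation) and guanylate-binding proteins (2 higher and 0 lower of 6, list alone 3 and 1, median 0.32, adjusted p = 0.0234, adjusted p = 0.379 with an estimated correlation) leaned the same way. MHC class II did not pass (0 higher and 2 lower of 13, list alone 1 and 3, median -0.094, adjusted p = 0.183). Here 2746 genes rose and 2020 fell, 202 and 39 by at least 2-fold, with GBP1 (5.31), GBP4 (4.98), IRF1 (4.01) and IDO1 (3.85). Of the genes called, 1661 rose in both experiments where 495.4 would be shared under independence, 1393 fell in both (322.5 expected), and 22 went in opposite directions (Pearson r = 0.859 across genes). MHC class I (18 higher and 0 lower of 18, list alone 18 and 0, median 1.26, adjusted p = 7.75e-25) and class II (13 higher and 0 lower of 13, list alone 13 and 0, median 1.78, adjusted p = 1.09e-15) rose, with HLA-E (2.58), TAP1 (3.20), HLA-DRA (3.26) and CIITA (2.33). The chemokine list did not pass (3 higher and 0 lower of 5, list alone 3 and 0, median 0.31, adjusted p = 0.0853): CXCL10 reached 0.290 ± 0.028 RPKM (0.37 ± 0.10, adjusted p = 0.0145), CXCL11 0.119 ± 0.045 (adjusted p = 0.206) and CXCL9 0.0693 ± 0.012 (adjusted p = 0.515). These verdicts depend on the scale. The list passed with one-sum scaling (adjusted p = 0.00976) and with voom (median 3.53, adjusted p = 0.00445). CXCL11 passed with a pseudocount of 0.1 (1.12, adjusted p = 0.0353) and voom (4.88, adjusted p = 4.44e-05), and CXCL9 with voom (adjusted p = 0.00312). CD274 rose by 1.05. POLR2A (-1.92), the fatty acid synthase FASN (-1.64) and KMT2D (-1.42) fell. One-sum scaling put 27.3% of 4727 calls above 0 against 57.6%, and 3003 genes were called without the first DMSO interferon library.

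In GSK126-treated cells interferon gamma raised the same families and the CXCR3 chemokines as well. HLA-DRA and CIITA reached their highest levels of any group. Stress-response and cholesterol genes fell, as lists only with the preset correlation (adjusted p = 0.118 and 0.17 with an estimated one). Of 4599 changed genes 2680 rose and 1919 fell, 261 and 24 by at least 2-fold, with GBP4 (5.53), GBP1 (5.52), IDO1 (5.51) and HLA-DRA (4.85) on top. CXCL10 rose by 2.48 ± 0.10, CXCL11 by 1.49 ± 0.095 and CXCL9 by 1.20 ± 0.096 (adjusted p = 4.56e-10, 4.19e-08 and 4.93e-07). MHC class II (13 higher and 0 lower of 13, list alone 13 and 0, median 2.54, adjusted p = 5.59e-20) rose with HLA-DRB1 (3.97) and CIITA (3.03), and CD274 with 1.73. Falls included MAP1LC3C (-2.06), DDIT4 (-1.53), ACKR3 (-1.38), CHAC1 (-1.20) and INSIG1 (-1.18), with lower stress-response (3 higher and 12 lower of 17, list alone 3 and 13, median -0.30, adjusted p = 4e-05, adjusted p = 0.118 with an estimated correlation), cholesterol (0 higher and 11 lower of 20, list alone 0 and 14, median -0.21, adjusted p = 4.06e-06, adjusted p = 0.17 with an estimated correlation) and histone genes (0 higher and 11 lower of 11, list alone 0 and 11, median -0.39, adjusted p = 3.76e-08, adjusted p = 0.0728 with an estimated correlation). ARID1A did not fall further (-0.14 ± 0.062, adjusted p = 0.116). One-sum scaling put 38.7% of 4889 calls above 0 against 58.3%.

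With interferon in both, GSK126-treated cells held more CXCR3 chemokine, MHC class II and IDO1 message than DMSO cells. Apart from the xenobiotic enzyme CYP1A1 (1.46), the 8 largest rises were in these families. Few genes moved by much: 659 were higher and 810 lower, 18 and 1 by at least 2-fold. CXCL10 stood at 4.74 ± 0.7 against 0.290 ± 0.028 RPKM (2.15 ± 0.10, adjusted p = 6.01e-08), CXCL11 at 1.83 ± 0.26 against 0.119 ± 0.045 (1.34, adjusted p = 4.41e-06) and CXCL9 at 1.31 ± 0.095 against 0.0693 ± 0.012 (1.11, adjusted p = 2.21e-05). The GSK126 levels are close to those of wild-type cells with interferon on PBS. IDO1 (ENSG00000131203.12, chromosome 8, 39902275 to 39928444) was at 45.3 ± 0.2 against 14.1 ± 0.93 RPKM (1.62 ± 0.065, adjusted p = 1.53e-08). MHC class II rose (12 higher and 0 lower of 13, list alone 12 and 0, median 1.03, adjusted p = 1.21e-24), with HLA-DRA at 29.1 ± 0.0075 against 8.62 ± 0.15 RPKM (1.65), HLA-DPA1 (1.77), HLA-DRB1 (1.52) and CIITA at 7.41 ± 0.31 against 4.05 ± 0.022 RPKM (0.73). Chemokines (5 higher and 0 lower of 5, list alone 5 and 0, median 1.11, adjusted p = 1.41e-10), MHC class I (8 higher and 0 lower of 18, list alone 11 and 0, median 0.18, adjusted p = 2.06e-09) and antiviral genes (16 higher and 0 lower of 39, list alone 26 and 0, median 0.21, adjusted p = 1.02e-14) all passed, with HLA-F (0.59), HLA-B (0.41), RSAD2 (0.70), OAS2 (0.53) and XAF1 (0.52). Guanylate-binding proteins (4 higher and 0 lower of 6, list alone 5 and 0, median 0.38, adjusted p = 4.47e-06, adjusted p = 0.0663 with an estimated correlation) and cholesterol genes (8 higher and 0 lower of 20, list alone 9 and 0, median 0.12, adjusted p = 1.56e-07, adjusted p = 0.136 with an estimated correlation) did so only with the preset correlation. IRF1 (0.22, adjusted p = 0.0182) was slightly higher. That call was lost with no filter (adjusted p = 0.059), with this experiment fitted alone (adjusted p = 0.0798) and with any 1 of its 4 libraries left out (adjusted p = 0.052 to 0.144), at values of 0.20 to 0.24. CD274 had no detected change (-0.067 ± 0.058, adjusted p = 0.48). Among the falls were the metallothionein MT1E (-0.73), the peptide hormone KISS1 (-0.72) and the protease ADAMTS1 (-0.65). The call count is not firm: 196 and 291 genes without the first and second DMSO interferon library, 156 and 551 without the GSK126 ones, 256 with the 8 libraries of this experiment fitted alone, and 63.6% of 1275 calls above 0 with one-sum scaling against 44.9%. The 174 genes raised at least 2-fold by interferon in wild-type PBS cells, other libraries, had a median of 0.24 here (p = 4.26e-47, p = 0.000225 with an estimated correlation), 98 called higher and 1 lower. The 98 fell to 46 and 50 without the first and second DMSO interferon library, 47 and 67 without the GSK126 ones and 59 with this experiment fitted alone.

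The interferon response itself was larger with GSK126 than with DMSO for chemokines, MHC class II and IDO1 on the log2(RPKM + 1) scale. For the chemokines this gain is measured against a weak DMSO response. With interferon CXCL10 was at 4.24 and 5.24 RPKM with GSK126 and 0.271 and 0.311 with DMSO. Wild-type cells on PBS, without GSK126, held 3.86 and 3.345. The test of the difference also called genes that already differed with GSK126 alone. POLR2A is the clearest of these, since it was already low with GSK126 before interferon. The difference of responses was called for 1795 genes, 1213 upward and 582 downward. This upward lean was not kept without the first GSK126 library. CXCL10 (2.11 ± 0.15, adjusted p = 1.59e-06), CXCL11 (1.33 ± 0.13, adjusted p = 3.1e-05) and CXCL9 (1.11 ± 0.14, adjusted p = 0.000139) responded more with GSK126, and the list passed (3 higher and 0 lower of 5, list alone 4 and 0, median 1.11, adjusted p = 3.07e-05). With voom these calls were lost at values no smaller: list median 2.46 (adjusted p = 0.0738), CXCL10 2.46 (adjusted p = 0.172) and CXCL11 3.19 (adjusted p = 0.0511). MHC class II passed (10 higher and 0 lower of 13, list alone 11 and 0, median 0.70, adjusted p = 9.89e-13), with HLA-DPA1 (1.67), HLA-DRA (1.59), HLA-DRB1 (1.46) and CIITA (0.70), and IDO1 was at 1.65 ± 0.092 (adjusted p = 3.11e-07). With voom HLA-DRA turned to -0.58 (adjusted p = 0.697) and HLA-DPA1 to -0.79 (adjusted p = 0.635). HLA-DRB1 fell to 0.11 (adjusted p = 0.959), so the larger response of these 3 genes, unlike their higher level, depends on the scale. The list held with voom (median 0.54, adjusted p = 0.0256). CIITA lost its call with a pseudocount of 0.1 at a similar value (0.56, adjusted p = 0.181). MHC class I leaned up (7 higher and 0 lower of 18, list alone 11 and 0, median 0.21, adjusted p = 0.000282, adjusted p = 0.167 with an estimated correlation), with HLA-B (0.39) and HLA-C (0.39). IRF1 was at 0.53, and CD274 at 0.68 from its lower start. Upward values for POLR2A (2.01), MKI67 (1.59), RAPH1 (1.48) and ARID1A (0.99), and downward ones for MT1X (-1.42), MT1E (-1.35), CHAC1 (-1.10) and DDIT3 (-0.99), mirror the change with GSK126 alone. Histone (0 higher and 11 lower of 11, list alone 0 and 11, median -0.48, adjusted p = 1.69e-12, adjusted p = 0.0667 with an estimated correlation) and stress-response genes (0 higher and 6 lower of 17, list alone 0 and 11, median -0.36, adjusted p = 7.93e-05, adjusted p = 0.165 with an estimated correlation) went down in the same way. The 174 interferon genes chosen in wild-type PBS cells had a median of 0.20 (quartiles 0.03 and 0.43, p = 3.34e-12, p = 0.0158 with an estimated correlation), 60 higher and 8 lower. Without the first GSK126 library 2898 genes were called, without the first DMSO interferon library 1056, without the first GSK126 interferon library 1068, and 1009 with this experiment fitted alone. Quantile normalization put 57.5% of calls above 0 against 67.6%.

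**Figure D2:**
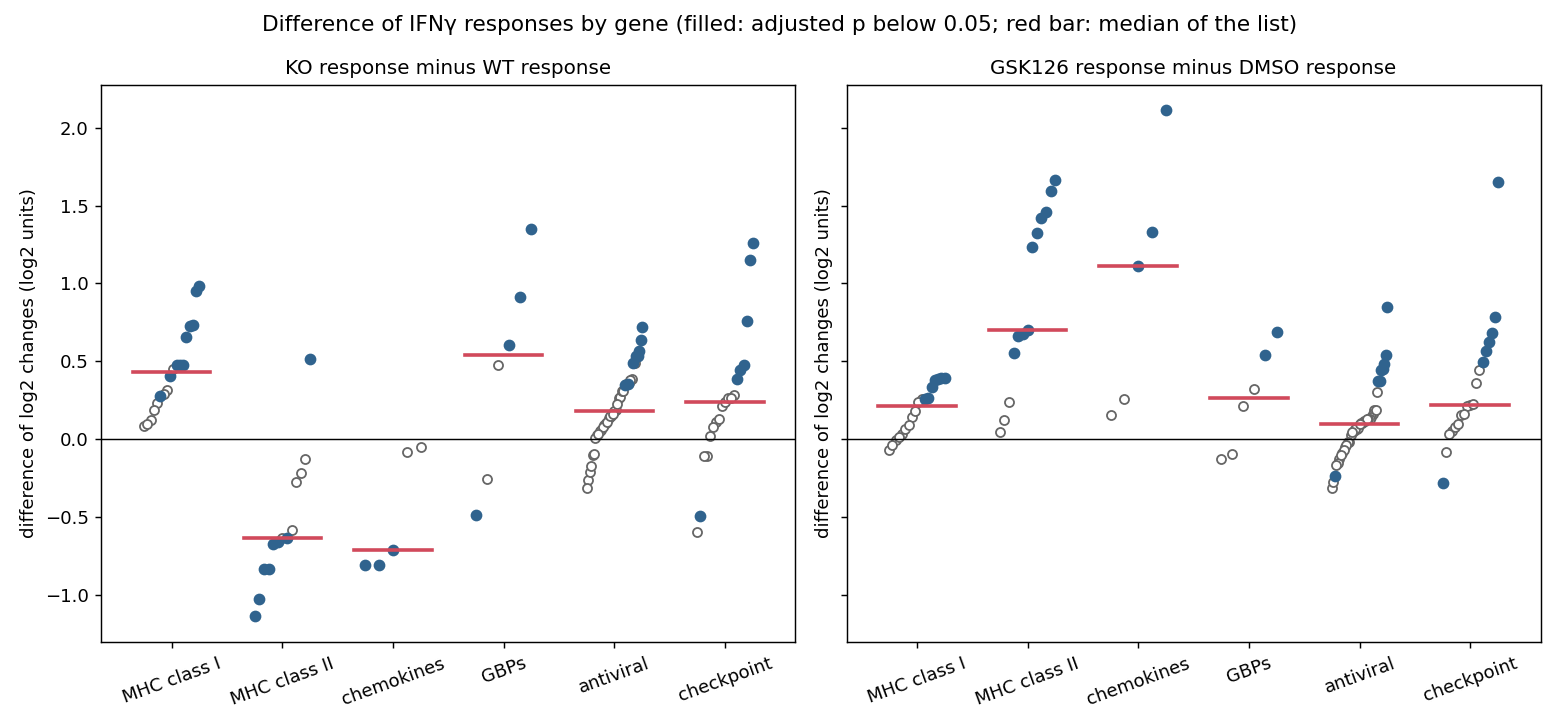
Difference of the interferon gamma log2 changes (vertical axis, log2 units) for each gene of 6 lists, knockout minus wild type on the left and GSK126 minus DMSO on the right; filled points have an adjusted p below 0.05 and red bars are list medians. MHC class II has a median of -0.64 on the left and 0.70 on the right, and the chemokines -0.71 and 1.11.

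The genes changed with the knockout label and with GSK126 lean in opposite directions, in comparisons that share no library. On PBS or DMSO, 749 genes were higher in the knockout and lower with GSK126 where 525.4 would be shared by independence (odds ratio 1.82, Fisher exact adjusted p = 1.57e-31), and 661 lower in the knockout and higher with GSK126 (407.9 expected, odds ratio 2.27, adjusted p = 3.15e-48). Same-direction overlaps were below that, 331 higher in both (357.4 expected, odds ratio 0.896, adjusted p = 0.098) and 490 lower in both (599.7 expected, odds ratio 0.733, adjusted p = 1.13e-08). With interferon opposite directions were again in excess, and no test compared this with the overlap on PBS or DMSO: 391 genes up then down (189.9 expected, odds ratio 3.33, adjusted p = 1.46e-56), 375 down then up (161.9 expected, odds ratio 4.43, adjusted p = 4.86e-73), 113 higher in both (154.5 expected, odds ratio 0.664) and 91 lower in both (199.1 expected, odds ratio 0.372). HLA-DRA (-1.33 with the knockout, 1.65 with GSK126), CIITA (-0.67 and 0.73), CXCL9 (-0.78 and 1.11), CXCL10 (-0.83 and 2.15) and CXCL11 (-0.63 and 1.34) are among those lower in the knockout and higher with GSK126. WFDC2 (-2.10 and 0.37) and HLA-F (-1.40 and 0.59) follow them. WFDC2 lost its GSK126 call with no filter, at the same 0.37 (adjusted p = 0.0752). Fisher's test treats genes as independent, so these p-values are too small. Of the 341 genes low in all treated groups, 111 were higher and 55 lower in the knockout on PBS. With GSK126 alone 286 of them were lower and 4 higher. A batch of the untreated libraries could thus add to the overlap on PBS or DMSO, although no library is shared. Between GSK126 and DMSO cells with interferon only 14 of them were lower and 7 higher. With interferon the genes in opposite directions numbered 95 to 714, and those in the same direction 28 to 181, as single libraries were left out.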

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

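The tests of length and GC content, scaling, TGF-beta targets, sequencing depth and olfactory reads were fixed before their results; the tests of additive effects, batch, the directions of 2-fold changes, vehicle, olfactory genes and EZH2 were chosen after the result was seen.

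The interferon response differed between the backgrounds by direct tests of the difference: 129 genes between the genotypes, 1795 between GSK126 and DMSO, and 143 between DMSO and PBS cells of the parental line. The last count is not firm, 17 to 86 with single libraries left out, lowest without the second wild-type PBS library. The interferon-induced sets had medians of 0.18 for the knockout and 0.20 for GSK126. What makes the DMSO and PBS responses of one line differ, with CXCL10 at -1.81, bears on both experiments. The CXCL10 gain with GSK126 is measured against the weak DMSO response. The CXCL10 response of the knockout lies between those of parental DMSO and PBS cells.

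A set of 341 genes, POLR2A, ARID1A and MKI67 among them, was low in every treated group: median -0.69 with interferon in wild type, -0.75 in the knockout, -0.62 in DMSO cells and -0.59 with GSK126 alone, but only -0.067 when interferon followed GSK126. A smooth trend with gene length or GC content over all tested genes is excluded, since the GSK126 median was still -0.50 after its removal. Genes of the set are long (median 5949 nt against 3225 for all tested). A trend fitted over all genes cannot exclude an effect on only part of the long transcripts. The changes with interferon and with GSK126 did not add up, as GSK126 left the set unchanged in interferon-treated cells (-0.0295). That value follows from the medians above, so it is no further test of additive effects. A handling or library batch holding the PBS and DMSO libraries could give the pattern: in 68% of the set all 6 of those libraries lie above the other 10, a value that an effect of both treatments with a common floor would give as well, so the test cannot tell.

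Untreated DMSO and PBS cells of the same line differed in 5884 genes, with KRT17 at -4.91 and MMP9 at -3.44. One scale factor per library cannot give the changes of at least 2-fold, with 26 genes higher and 132 lower, since it moves all genes one way. Smaller changes stay open to scaling (2546 of 5884 calls above 0, but 3698 of 6197 with one-sum scaling): that 100% of the 2-fold calls kept their direction under 3 other scalings decides nothing, as these shift the median change by at most 0.0609. Vehicle or a culture batch cannot be told apart: the difference recurred with interferon (Pearson r = 0.825 across genes), which either would produce. Lower TGF-beta signalling in the DMSO cells is a hypothesis whose prediction was met. In the interferon-treated pair 28 of 35 tested target genes were lower (median -0.54, camera p = 3.28e-14, p = 0.0121 with an estimated correlation). The untreated pair, where the hypothesis arose, also had 28 lower. As the differences of the pairs correlate (r = 0.825), the interferon-treated pair is no independent test and could hardly fail. The cause of such a shift was not tested.

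The libraries with GSK126 alone list 33399 and 29547 genes above 0, against at most 27518 elsewhere. Depth is excluded, since at 40 M reads they still hold 30230 and 26661 against at most 25335. Silent genes turned on by EZH2 inhibition stay open: the libraries with GSK126 and interferon hold 24372 and 24063, above their DMSO counterparts (22812 and 23609) but by less than the excess with GSK126 alone. Spread of reads over the genome, as from genomic DNA, may explain it: 103 and 50 olfactory receptor genes and pseudogenes held a read at equal depth, against 28 to 41 in all other libraries but the second DMSO one (54). The earlier form of that test, olfactory reads per M reads, gave 7.95 and cannot tell, because OR2W3 takes 87.4% of those reads and its prediction wrongly assumed they were background.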

How the results depend on the processing

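The tests here were planned before the data were examined except voom, the fit without the GSK126 group and the comparisons of DMSO with PBS cells, tests chosen after the result was seen. Pseudocount 0.1, a filter at 5 RPKM, all 3 other scalings, no trend, robust fitting, voom and a replicate block kept all 20 counts and sets, counts within a factor of 1.5 and sets past their threshold in the same direction. Within that bound they moved: quantile normalization gave 1217 genes against 1469 for GSK126 with interferon, and voom a median of 0.13 against 0.20 for the induced set in the difference of treatments. The replicate block carries little, as the numbers 1 and 2 share only a label (residual correlations of -0.11 to 0.22, above 0.1 in 4 of 28 pairs). The largest shift of all genes came from one-sum scaling, -0.123 in the median for interferon in the knockout and -0.101 in DMSO cells. Shares of calls above 0 under quantile normalization were 45% (interferon, knockout), 43.7% (interferon, DMSO), 40.4% (interferon, GSK126) and 55.4% (GSK126 with interferon, 60.4% with median of ratios) against 55.4%, 57.6%, 58.3% and 44.9%. An estimated correlation ended 54 of the 97 list calls. Requiring 2-fold left 230 (interferon, wild type), 375 (knockout on PBS), 273 (interferon, knockout), 365 (knockout with interferon), 9 (difference of genotypes), 57 (GSK126), 241 (interferon, DMSO), 285 (interferon, GSK126), 19 (GSK126 with interferon) and 71 genes (difference of treatments). Leaving out single libraries gave 3053 to 3493 genes for interferon in wild type, 3529 to 4960 in the knockout, 3003 to 3648 in DMSO cells, 61 to 118 for the difference of genotypes, 156 to 551 for GSK126 with interferon and 1056 to 2898 for the difference of treatments. GSK126 with interferon gave 558 genes with no filter, 256 with its own experiment fitted alone and 2526 without the GSK126 group. The difference of treatments gave 1009 with its own experiment alone, and the difference of genotypes 216 without the GSK126 group. Overlaps with interferon in opposite and the same directions were 275 and 70 with no filter, 156 and 38 by experiment, 1366 and 380 without the GSK126 group, and 95 to 714 and 28 to 181 with single libraries left out. Genes with opposite responses to interferon in the parental cells numbered 13, 14 and 50 under those 3 alternatives and 8 to 15 with libraries left out. The ARID1A call was lost with no filter (0.19, adjusted p = 0.0617) and one-sum scaling (0.18, adjusted p = 0.0575), and ran from 0.12 (adjusted p = 0.218) to 0.26 with libraries left out. EZH2 with GSK126 was 0.15 (adjusted p = 0.0653) by experiment and 0.12 (adjusted p = 0.0745) to 0.18 with libraries left out. The lower interferon set of the knockout was lost with an estimated correlation (-0.11, p = 0.212) and with a 4-fold minimum (-0.071, p = 0.0896). Quantile normalization turned 3 lists: proliferation for interferon in the knockout (-0.085, adjusted p = 0.00631), and ribosomal proteins for interferon in DMSO cells (-0.0048) and for the difference of treatments (0.0078). Some single genes turned in the difference of genotypes: GBP5 with a pseudocount of 0.1 (0.44, adjusted p = 0.688) and voom (1.13, adjusted p = 0.483), and with voom CSF1 (1.055, adjusted p = 0.312), TRAF1 (0.10, adjusted p = 0.93) and HLA-DRA (2.56, adjusted p = 0.138). In the difference of treatments HLA-DRA (-0.58, adjusted p = 0.697) and HLA-DPA1 (-0.79, adjusted p = 0.635) turned with voom. With each experiment fitted alone CXCL9 and CXCL11 lost their calls in the difference of genotypes (-0.81, adjusted p = 0.0569, and -0.71, adjusted p = 0.0566), and IRF1 and WFDC2 lost theirs between GSK126 and DMSO cells with interferon (0.22, adjusted p = 0.0798, and 0.37, adjusted p = 0.0599). The cause of these moves was not tested.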

Other observations

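The tests of vehicle and batch quoted here were chosen after the result was seen, as were the comparisons of DMSO with PBS cells.

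DMSO cells differed from PBS cells of the same line in mesenchymal, MHC class I and cholesterol genes. Mesenchymal genes were lower (0 higher and 10 lower of 11, list alone 0 and 10, median -0.83, adjusted p = 4.94e-08), with THBS1 (-2.01), TGFBI (-1.74) and transgelin (-2.85 for TAGLN). MHC class I was lower (0 higher and 17 lower of 18, list alone 0 and 17, median -0.55, adjusted p = 5.71e-11, adjusted p = 0.05 with an estimated correlation), with HLA-B (-1.14), cholesterol genes were higher (15 higher and 0 lower of 20, list alone 16 and 0, median 0.37, adjusted p = 1.73e-08, adjusted p = 0.143 with an estimated correlation), with INSIG1 (1.14), and KRT17 fell from 212 ± 6.4 to 6.08 ± 0.099 RPKM. Vehicle or batch could produce this and the data cannot separate them (Pearson r = 0.825 between the untreated and interferon-treated differences).

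The same pair differed in chemokine response. CXCL10 reached 3.60 ± 0.36 RPKM with interferon on PBS and 0.290 ± 0.028 on DMSO, a difference of responses of -1.81 ± 0.15 (adjusted p = 0.000199), with CXCL11 at -1.32, CXCL9 at -1.05 and the ubiquitin-like UBD (-1.91). With voom the calls were lost, though not the size, for CXCL10 (-2.42, adjusted p = 0.331), CXCL11 (-3.09, adjusted p = 0.164) and UBD (-1.78, adjusted p = 0.536). The same held for CXCL9 with a pseudocount of 0.1 (-3.02, adjusted p = 0.0511). The chemokine list passed (0 higher and 3 lower of 5, list alone 0 and 3, median -1.05, adjusted p = 1.13e-06), while CIITA and IRF1 showed no detected difference (adjusted p = 0.596 and 0.992). GSK126 brought CXCL10 to 4.74 ± 0.7 RPKM, so GSK126 may restore a level that the DMSO cells do not reach or add a new response, and r = 0.825 cannot tell vehicle from batch as the source of the low DMSO level. DMSO cells do respond on other scales, with voom for CXCL11 (adjusted p = 4.44e-05) and CXCL9 (adjusted p = 0.00312). No group here combines GSK126 with PBS, so the data cannot tell which of these holds.

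CD274 parted from the chemokines. It was highest in the knockout with interferon (36.4 ± 2.5 RPKM), lowest with GSK126 alone (4.49 ± 0.36) and with no detected difference with interferon between DMSO and GSK126 cells (18.1 ± 0.1 and 17.2 ± 0.31, adjusted p = 0.48).

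INSIG1 and DDIT3, higher with GSK126 alone than with DMSO, were lower when interferon followed. INSIG1 went from 73.5 ± 11 to 31.7 ± 0.17 RPKM and DDIT3 from 13.3 ± 1.8 to 5.96 ± 0.014, near the DMSO values with interferon (30.1 ± 1.8 and 6.15 ± 0.061). Between GSK126 and DMSO cells the higher levels thus rest on the libraries with GSK126 alone. These differ most within their group (chi-square 15.9 per degree of freedom) and list more genes above 0. An effect of interferon cannot be told here from a trait of those libraries.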
